A study of Drosophila melanogaster with 2 samples.

How the data were processed

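Poly(A) RNA from heads of adult males of the w1118 laboratory strain of Drosophila melanogaster, also written w118 in the labels, was measured on 2 Affymetrix DrosGenome1 arrays, short-oligonucleotide arrays that read each transcript with 1 or more probe sets. Per the labels, males were collected within a day of eclosion and kept in the dark at 25 °C and 70% humidity at about 200 flies per bottle. Heads were freed in liquid nitrogen and passed through a sieve that held back the bodies, and RNA was extracted with Trizol and purified on an oligo(dT) resin, per the labels' protocols. The array of the unexposed group was made from heads at adult day 3. The array of the paraquat group was made from heads at adult day 3 after 30 h on sucrose containing 15 mM paraquat, started at adult day 2. Each group held 1 array, so no test across replicates was made and no p-value was computed. Groups were taken from the sample titles.

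The deposited values are intensities on a linear scale, 1 per probe set, with negative values where background or mismatch signal exceeded the probe signal. The authors' scaling was read from the values: the mean after removal of 2% of probe sets at each end was 2500 on both arrays, control probe sets included. The software that summarised the probes, its version and the detection calls are not given in the sources used here. Each array held 14010 probe sets, of which 44 were controls and 13966 were not. The deposited medians over the 13966 were 815.6 on the unexposed array and 834.8 on the paraquat array.

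Each array was scaled to the common median of 825.2 over the 13966 probe sets, by factors of 1.01 (unexposed) and 0.99 (paraquat). A floor was then set at the 40th percentile of the mean of both scaled arrays, an intensity of 477.3, and log2 was taken. Ratios are paraquat over unexposed. A probe set was called measured where it reached the floor on both arrays, and only measured probe sets were counted and ranked. Where 1 array was under the floor, the difference is given as "at least N-fold", from the value of the brighter array over the floor. Where both were under it, no ratio is given. On the paraquat array the highest absent control (a probe set for a transcript not in the sample) stood at 533, above the floor, and 118 measured probe sets, 34 of them counted as at least 2-fold lower, were not above it. Genes named among these (Mtk, wrapper, Yp1 and Atg2) are given a bound against that control or no ratio. Against it the other "at least" values for genes lower with paraquat would be 1.12 times smaller. Genes with several probe sets took the mean log2 ratio of the measured ones.

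Probe sets were named from a platform annotation dated 2016. Of the 13966, 12443 had 1 gene symbol, 327 had several and 1196 had none. Probe sets with several symbols were left out of the gene lists and rankings, and those in the closing observations are given as shared. Gene identifiers of 12394 of the single-symbol probe sets matched the NCBI RefSeq gene table of assembly Release 6 and 49 did not. That table was used for names alone, and no coordinates are printed, because the build behind the arrays is not given in the sources used here. Of the symbols in the gene lists, 3 (RpL37a, Trh and Dat) had no match.

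The array error of a log2 ratio is 1 SE built from control probe sets. Its additive part is the SD of the scaled intensities of absent controls, 358.3 over 46 values. Its proportional part is the SD of the log2 ratios of 9 spiked-in control probe sets, 0.12. It covers array and hybridisation error and leaves out the spread between flies, between RNA preparations and between bottles. It came to 1.54 at the floor on both arrays and 0.19 at 10 times the floor. The number of arrays limits the precision of every value.

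The genes named in the text follow a rule fixed before the data were examined: the 12 highest and 12 lowest log2 ratios among measured probe sets with 1 gene symbol, the 4 largest at-least-fold differences in each direction, and up to 4 genes with the largest absolute log2 ratio in each list. Named outside the rule, after their values were seen, are Def, AttD, TotB, stv, Mst57Da, Mst84Dd, Acp95EF, apolpp, Apoltp, RpS30, CG8036, Taldo, InR, PGRP-SC2, Cat and Sod2. So are the probe sets shared by several genes and the members of gene families in the closing observations. Also fixed at that point were 24 gene lists: glutathione S-transferases, cytochrome P450s, UDP-glycosyltransferases, antioxidant enzymes, NADPH-producing enzymes, heat shock proteins, heat shock cognates and ER chaperones, metallothioneins and iron proteins, antimicrobial peptides, Turandot stress peptides, other immune genes, glycolysis, tricarboxylic acid cycle, respiratory chain and ATP synthase, proteasome, cytosolic ribosomal proteins, fasting and nutrient response, fatty acid synthesis, apoptosis and JNK pathway, DNA repair, autophagy, circadian clock, monoamine synthesis and transport, and odorant-binding proteins. Another 9 lists held markers of photoreceptors, neurons, glia, head fat body, muscle, haemocytes, gut, the male reproductive tract and female-specific products. For each list the median log2 ratio over measured genes was set against the medians of 10000 random gene lists of the same size, matched on mean log2 level in 20 bins. A median in the outer 5% of the random lists is called outside the random range. This describes these 2 arrays and is no test of the treatment.

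The procedure was tested on simulated data for the comparison of paraquat with unexposed, in 20 runs of 13966 probe sets with array error alone and 200 probe sets changed per run. On average 110.4 unchanged probe sets came out at least 2-fold higher and 106.7 at least 2-fold lower. The changed probe sets were drawn from those with a mean intensity above 2 times the floor, so recovery nearer the floor was not simulated. Of the measured probe sets simulated with a log2 change of 1.5, 89.6% passed 2-fold, as did 100% of those with a log2 change of 3. Of 20 simulated lists of 20 genes shifted by 0.50 on the log2 scale, 20 came out outside the random range, against 0 of the unshifted lists. The log2 ratios of the real arrays had an SD of 0.81, and many lists held fewer than 20 genes. A shift of 0.50 in such a list may therefore stay inside the random range.

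The alternatives planned were the values without rescaling, quantile normalization, scaling to a 2% trimmed mean, loess of the log2 ratio on mean log2 level (span 0.40), floors at the 20th and 60th percentiles, a pseudocount equal to the floor in place of the floor, ratios of 1.5 and 3 in place of 2, the brightest probe set of a gene, the mean of a list in place of its median, and list members under the floor on 1 array kept at the floor. Floors at the 30th and 80th percentiles and a count restricted to ratios beyond the 95% interval of array error were added after the data had been seen. Control probe sets were left out of all counts and lists. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.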

Results

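Transcript levels in the heads of adult male flies were measured on 2 arrays, 1 from unexposed flies and 1 from flies fed 15 mM paraquat in sucrose for 30 h, both harvested at adult day 3. Paraquat is a herbicide that cycles between redox states inside cells and produces superoxide, and the study used it to ask how oxidative stress alters gene expression in the head. At or above the floor were 8333 of 13966 probe sets (59.7%) on the unexposed array and 8366 (59.9%) on the paraquat array. Both arrays measured 7425 probe sets, and across these probe sets, which are not independent replicates, the log2 intensities correlated with a Pearson r of 0.88. The labels describe the unexposed flies as kept in food bottles and the paraquat flies as moved to sucrose, so diet may differ between the arrays along with paraquat. An array of flies on plain sucrose was not analysed here.

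Heat shock proteins and proteasome subunits had higher median levels on the paraquat array, as did glutathione S-transferases and DNA repair genes, whose results depended on the floor. Lower medians were found for antimicrobial peptides, head fat body products, odorant-binding proteins, the list named fatty acid synthesis and the mitochondrial respiratory chain. Markers of the male reproductive tract, which is not part of the head (-1.43), of muscle (-0.67) and of the gut (-0.62) had lower medians on the same array. GstD2, which conjugates glutathione to electrophiles, was 29.5-fold higher, from an intensity of 2092 to 61628 (log2 4.88 ± 0.27, array error). The storage protein Lsp2 was 210-fold lower, from 113535 to 539 (log2 -7.72 ± 0.97), a value close to the highest absent control (533), a probe set for a transcript not in the sample, on the paraquat array. The antifungal peptide Mtk was at least 141-fold lower, from 75369 to 526, which is not above that control. Transcripts of photoreceptors, neurons and cytosolic ribosomes differed little between the arrays. No difference in this comparison has a replicate check, because each group held 1 array.

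Of the 7425 measured probe sets, 605 (8.15%) were at least 2-fold higher on the paraquat array and 610 (8.22%) at least 2-fold lower. Array error alone gave 110.4 higher and 106.7 lower in simulation, and 425 higher and 455 lower probe sets also lay beyond the 95% interval of array error. Among the 12 highest ratios, GstD2 was followed by CG16898 (26.0-fold, log2 4.70 ± 0.36), CG10383 (20.5-fold, log2 4.36 ± 0.32) and the cytochrome P450 Cyp4e3 (12.3-fold, log2 3.62 ± 0.25). The tetraspanin Tsp42Ed, CG7130, CG11825 and the tryptophanyl-tRNA synthetase TrpRS were between 11.3-fold and 9.93-fold higher. CG30269, MME1, CG5958 and the inducible chaperone Hsp68 were between 9.24-fold and 8.35-fold higher. After Lsp2 and Mtk, the lowest ratios belonged to CG2736 (log2 -5.21 ± 0.59), the peptide hormone CCHa2 (log2 -4.24 ± 0.41), CG9396 (log2 -4.15 ± 0.64) and the odorant-binding protein Obp56e (log2 -4.07 ± 0.39). CG7322, the fat body gene sxe2, the antibacterial peptide DptB, CG4757, the immune-induced peptide BomBc3 and Had1 had log2 ratios between -4.05 and -3.66.

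**Figure D1:**
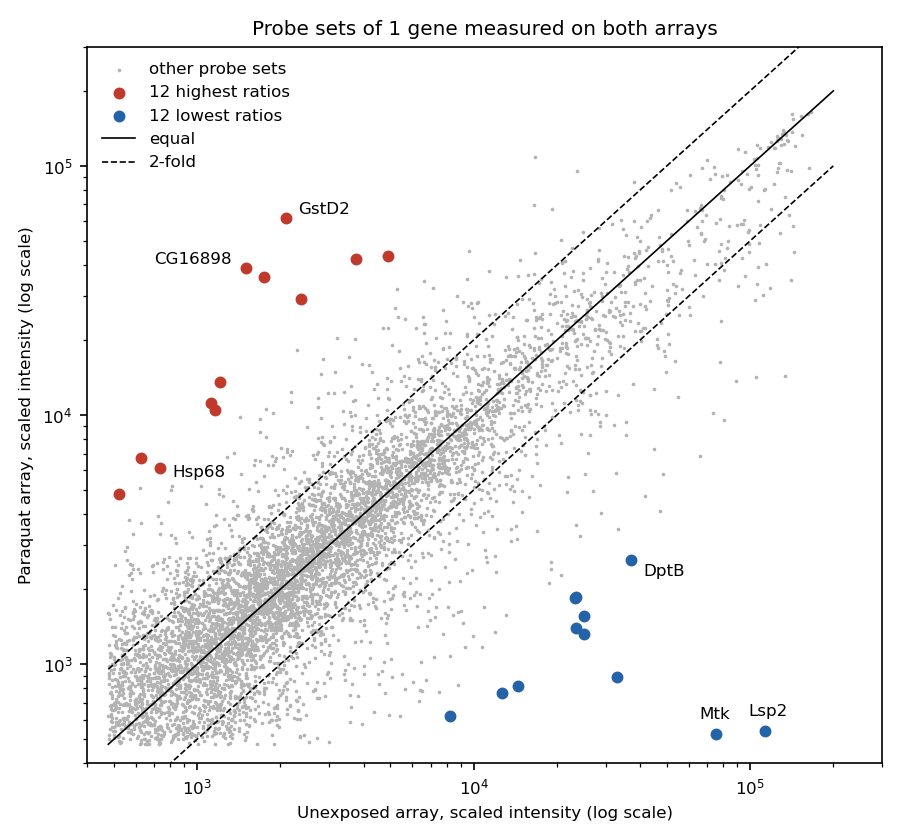
Scaled intensity of each probe set of 1 gene measured on both arrays, unexposed on the x axis and paraquat on the y axis, both on log scales, with lines for equal intensity and for a 2-fold difference. The 12 highest ratios (red) run from Hsp68 at 8.35-fold to GstD2 at 29.5-fold, and the 12 lowest (blue) include Lsp2 at 113535 on the unexposed array and 539 on the paraquat array.

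Several genes were above the floor on 1 array alone, so that only a bound can be given. The small heat shock gene Hsp26 was at least 61.3-fold higher on the paraquat array, GstE11 at least 26.3-fold, CG5697 at least 22.9-fold and Dgat2, which makes triglycerides, at least 12.2-fold. In the other direction, the fat body peptide gene fit was at least 96.5-fold lower, the insulin-responsive glucosidase gene tobi at least 70.7-fold, the peptidoglycan recognition gene PGRP-SB1 at least 59.5-fold and CG15353 at least 21.5-fold.

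**Figure D2:**
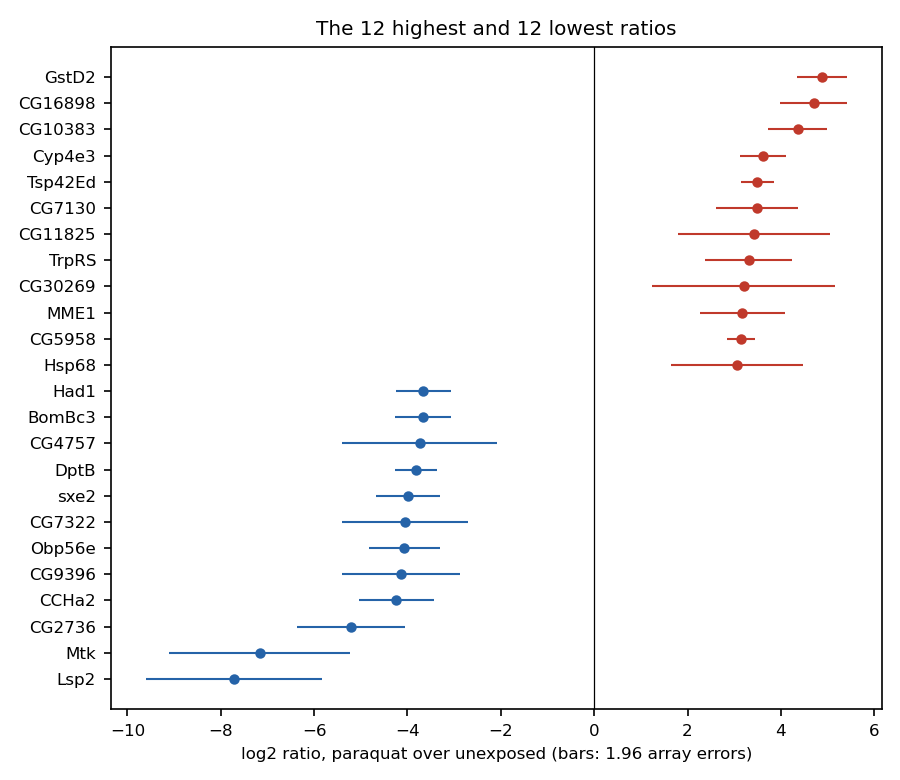
Log2 ratio of paraquat over unexposed for the 12 highest (red) and 12 lowest (blue) ratios, with bars for the 95% interval of array error, which cover array and hybridisation error alone. Each bar stays on its own side of 0, and the widest belong to genes near the floor on 1 array, such as CG30269 and Lsp2. The point for Mtk is a bound, as its paraquat value is not above the highest absent control.

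Among detoxification genes, 9 of 28 measured glutathione S-transferases were at least 2-fold higher and 1 at least 2-fold lower. The list median was 0.29 (percentile 99.4 of matched random lists, whose middle 95% ran from -0.26 to 0.23), and 13 of the 28 had ratios below 0. With the floor at the 60th and 80th percentiles the median was 0.14 and 0.05, inside the random range. Behind GstD2 came GstD5 (8.15-fold higher, log2 3.03 ± 0.84), GstE8 (5.65-fold) and GstD3 (4.62-fold). Cytochrome P450s went both ways, with 8 of 49 at least 2-fold higher, 7 at least 2-fold lower and a median of -0.14 inside the random range. Cyp4e3 was the highest, while Cyp313a1, Cyp4g1 and Cyp305a1 were 8.37-fold, 8.32-fold and 7.97-fold lower. Of 6 UDP-glycosyltransferases, Ugt37D1 was 5.18-fold higher, Ugt35B1 4.27-fold lower and Ugt317A1 2.42-fold lower, with Ugt302C1 1.92-fold higher and a list median of -0.15 inside the random range (0.94 and outside it with the 3 genes above the 80th percentile floor).

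The classical antioxidant enzymes that were measured did not stand apart as a group, with 3 of 18 at least 2-fold higher, 2 at least 2-fold lower and a median of -0.12 inside the random range. Of 26 listed, 19 had a probe set of their own, and Sod1 was not among them. Cat was 1.62-fold higher (log2 0.70 ± 0.12) and Sod2 1.69-fold lower (log2 -0.76 ± 0.13). Thioredoxin reductase Trxr1 was 2.88-fold higher (log2 1.53 ± 0.13), the carbonyl reductase sni 2.63-fold and the glutathione peroxidase Gtpx 2.43-fold. The extracellular superoxide dismutase Sod3 was 3.62-fold lower, with log2 ratios from -3.29 to -0.90 over its 3 probe sets. In the list named NADPH-producing enzymes, all 6 measured genes were lower, 1 of them (Rpi) at least 2-fold. The median was -0.71 (percentile 1.48, random range -0.60 to 0.58, and inside that range at both higher floors). Rpi, CG8036 and Taldo belong to the non-oxidative pentose phosphate branch, which makes no NADPH. The NADPH makers measured were Men, Men-b and Idh, none of them past 2-fold, and Zw and Pgd had no probe set of their own. The medians of head fat body (-2.79), male reproductive tract (-1.43), muscle (-0.67) and gut enzymes (-0.62) were lower on the same array. Rpi had a log2 ratio of -1.21 ± 0.58, Men -0.87, Men-b -0.79 and Idh -0.62. Among 10 metallothioneins and iron proteins, 1 was at least 2-fold lower, the transferrin Tsf1 (6.49-fold). MtnB (log2 -0.79 ± 0.88), Tsf3 (-0.76) and the ferritin Fer2LCH (0.55) differed less, and the list median of -0.25 lay inside the random range.

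Heat shock proteins and the proteasome were higher on the paraquat array. All 6 measured heat shock genes with a probe set of their own had ratios above 0, and 3 were at least 2-fold higher, with a median of 0.99 (percentile 99.8, random range -0.58 to 0.61). Hsp68 (8.35-fold) and Hsp27 (5.18-fold) led, followed by DnaJ-1 (2.02-fold) and the mitochondrial chaperone Hsp60A (log2 0.97). For stv, the lowest of the 6 and named after its values were seen, the probe sets differed in sign (log2 -1.26 and 1.41). All 26 measured proteasome subunits were higher, 19 of them at least 2-fold, and the median of 1.20 lay above all 10000 random medians (middle 95% from -0.24 to 0.27). The largest differences were in the lid deubiquitinase Rpn11 (3.64-fold), the core subunits Prosalpha6 (3.61-fold) and Prosbeta2 (3.45-fold) and the base ATPase Rpt4 (3.08-fold). Chaperones of the endoplasmic reticulum and heat shock cognates were mixed, with 3 of 12 at least 2-fold higher, 2 at least 2-fold lower and a median of 0.32 inside the random range. That median was outside it under quantile normalization (0.43) and loess (0.37), and below 0 with the floor at the 60th (-0.31) and 80th (-0.33) percentiles. ERp60 was 2.78-fold and Gp93 2.66-fold lower, whereas Edem2 was 2.08-fold higher and Hsc70-1 2.55-fold higher with a wide array error (log2 1.35 ± 0.84).

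Of 8 measured DNA repair genes, 4 were at least 2-fold higher and none at least 2-fold lower, with a median of 0.998 (percentile 99.9, random range -0.53 to 0.58). These were Ku80 (log2 1.44 ± 0.93), rad50 (1.29 ± 0.31), mre11 (1.09 ± 0.49) and Xpc (1.05 ± 0.56), which act in double-strand break or nucleotide excision repair, and another 3 genes of the list were above the floor on the paraquat array alone. With the floor at the 60th percentile 1 gene of this list was left, and at the 80th none. In the apoptosis and JNK pathway list, 1 of 11 genes was at least 2-fold higher, p53 (5.04-fold, log2 2.33 ± 0.53). The transcription factors kay (1.92-fold) and Jra (1.91-fold) and the JNK phosphatase gene puc (1.62-fold) were also higher, and the list median was 0.21, inside the random range (0.64 and outside it with the floor at the 60th percentile). In autophagy, 1 of 14 genes was at least 2-fold higher, the ubiquitin-binding adaptor gene ref(2)P (4.75-fold, log2 2.25 ± 0.13). Atg18a (1.92-fold) and Atg1 (1.59-fold) were higher and Atg2 was not above the highest absent control on the paraquat array, for a median of 0.13 inside the random range.

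**Figure D3:**
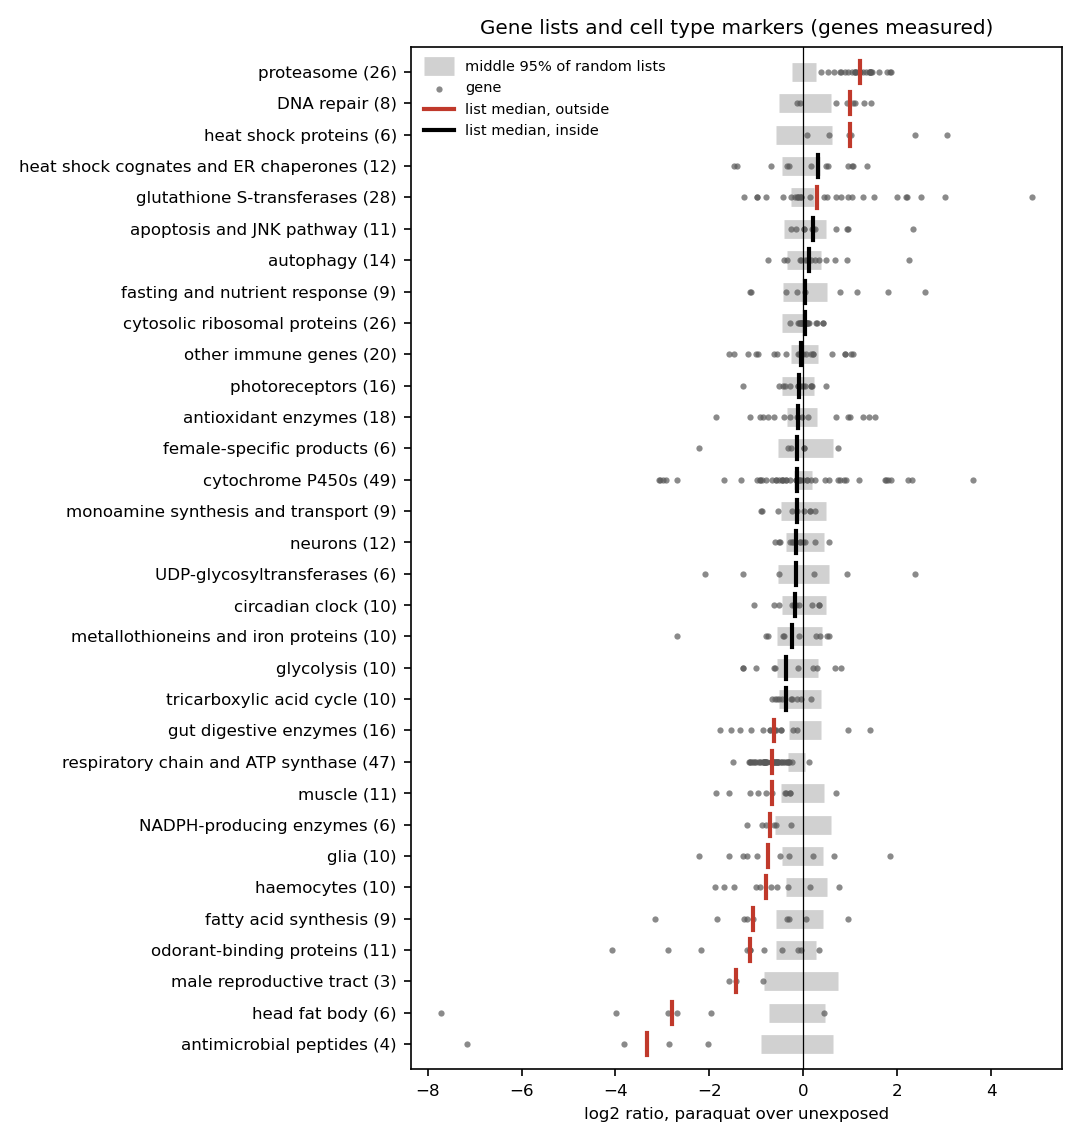
Log2 ratio of paraquat over unexposed for the measured genes (dots) of each gene list and marker list, with the list median (red outside, black inside the random range) and the middle 95% of medians of 10000 random lists matched on size and level (grey bars). The proteasome has the highest median at 1.20 and antimicrobial peptides the lowest at -3.34, and the photoreceptor median of -0.10 changes sign under quantile normalization (0.12) and loess.

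Antimicrobial peptides and fat body products were the groups furthest below the unexposed array. All 4 measured antimicrobial peptides were at least 2-fold lower, with a median of -3.34 below all 10000 random medians (middle 95% from -0.90 to 0.63). After Mtk, DptB was 14.1-fold lower, Drs 7.24-fold and Drsl5 4.06-fold, and Def and AttD, under the floor on the paraquat array and named after their values were seen, were at least 16.2-fold and at least 4.31-fold lower. Of the Turandot stress peptides, 1 had a probe set of its own (TotB), which was under the floor on both arrays. Other immune genes were mixed, with 2 of 20 at least 2-fold higher, 4 at least 2-fold lower and a median of -0.05 inside the random range. Another 2 were under the floor on the paraquat array and outside these counts: PGRP-SB1 (at least 59.5-fold lower) and PGRP-SC2 (at least 5.49-fold lower). With both kept at the floor the median was -0.11, inside the random range. GNBP3 (2.99-fold), the prophenoloxidase PPO1 (2.79-fold) and the serpin nec (2.27-fold) were lower, and the NF-κB inhibitor cact was 2.09-fold higher. Of 6 measured head fat body markers, 5 were at least 2-fold lower, with a median of -2.79 below all random medians (middle 95% from -0.74 to 0.47). With fit kept at the floor the median was -2.89. Besides Lsp2 and sxe2, Obp99b was 7.41-fold lower and Tsf1 6.49-fold lower, both of which also belong to another list. Transcripts of the male reproductive tract, which is not part of the head, were more abundant on the same unexposed array, with 19 of 25 probe sets at or above the floor there against 3 on the paraquat array.

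In the list named fatty acid synthesis, 5 of 9 measured genes were at least 2-fold lower and none at least 2-fold higher, with a median of -1.08 (percentile 0.08, random range -0.58 to 0.43). The list is wider than its name: its lowest gene, the acyl-CoA synthetase bgm (8.89-fold lower), activates existing fatty acids. The fatty acid synthase FASN1 was 3.56-fold lower, AcCoAS 2.41-fold and the acetyl-CoA carboxylase ACC 2.28-fold. The head fat body markers were lower on the same array (median -2.79, 5 of 6 at least 2-fold). The fasting and nutrient list went both ways, with 3 of 9 genes at least 2-fold higher, 2 at least 2-fold lower and a median of 0.04 inside the random range (0.41 and 0.93, outside it, with the floor at the 60th and 80th percentiles, and -0.05, inside it, with members kept at the floor). Those members include fit and tobi, at least 96.5-fold and 70.7-fold lower, and InR, at least 3.59-fold higher. The list mixes genes that fasting raises with genes that it lowers, so opposite changes can cancel in its median. The lipase genes Lip4 (6.04-fold) and bmm (3.50-fold) and the sestrin gene Sesn (2.21-fold) were higher, and the insulin-like peptide gene Ilp2 was lower (log2 -1.14 ± 0.18).

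Of 47 genes of the respiratory chain and ATP synthase, 46 were lower on the paraquat array, 8 of them at least 2-fold. The median of -0.66 lay below all 10000 random medians (middle 95% from -0.32 to 0.05). The catalytic subunit ATPsynbeta was 2.82-fold lower (log2 -1.50 ± 0.12), ND-B18 of complex I 2.23-fold, and ATPsynF (log2 -1.14) and ATPsynO (-1.13) by similar amounts. Muscle markers differed by a similar amount, with a median of -0.67 over 11 genes. No gene of the tricarboxylic acid cycle passed 2-fold, and the median of 10 genes was -0.36, inside the random range, with SdhD (-0.67), Idh3g (-0.60), mAcon1 (-0.56) and SdhC (-0.52) lowest. In glycolysis, 3 of 10 genes were at least 2-fold lower, Hex-C (2.44-fold), Gpdh1 (2.43-fold) and Pgk (2.01-fold), while Hex-A was 1.75-fold higher and the median of -0.36 lay inside the random range. None of 26 cytosolic ribosomal protein genes passed 2-fold. Their median was 0.03, inside the random range (outside it after loess, at 0.19, and with the floor at the 80th percentile, at 0.03), and RpS12 (1.34-fold), RpL28 (1.33-fold) and RpS29 (1.22-fold) were higher and RpLP0 1.21-fold lower. Some of these genes, such as RpS30 (162626 unexposed, 161655 paraquat), stood near the highest deposited intensities (167877 and 167034). Whether this narrowed their ratios was not tested.

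Markers of photoreceptors and neurons were close to equal on both arrays. The median of 16 photoreceptor genes was -0.10, and 0.12 after quantile normalization, with eys (2.44-fold lower over 2 probe sets) the only gene past 2-fold in the list and chp (-0.51), rdgC (0.48) and inaD (-0.44) next. None of 12 neuronal genes passed 2-fold (median -0.14), and Rab3 (-0.60 ± 1.12), unc-13 (0.54), Csp (-0.51) and ChAT (-0.49) differed most. Of 10 circadian clock genes, per was 2.08-fold lower (log2 -1.05 ± 0.97), cry and tim had log2 ratios of -0.61 and -0.51 (tim 0.10 with the pseudocount in place of the floor) and the kinase dco 0.34, and the median was -0.18. No monoamine gene passed 2-fold among 9 (median -0.14), with Pu at -0.91, DAT at -0.89 ± 0.71, Vmat at -0.54 and Tbh at 0.26 ± 1.37. These 4 medians all lay inside the random range. Odorant-binding proteins stood apart, with 6 of 11 at least 2-fold lower and none at least 2-fold higher (median -1.13, percentile 0.03, random range -0.58 to 0.27). Obp56e, Obp99b, Obp56h (4.50-fold lower) and Obp57c (2.29-fold lower) led this list, and with another 5 genes kept at the floor the median was -0.83. Obp99b is also a head fat body marker, and the medians of head fat body, male reproductive tract, gut enzymes and muscle were lower on the same array, as given above. Glial markers had a median of -0.75 over 10 genes (percentile 0.15, random range -0.45 to 0.43, and -0.40 and inside the range at both higher floors), with wrapper (at least 4.56-fold, not above the highest absent control on the paraquat array), rumpel (-1.58) and Inx2 (-1.28) lower and loco (1.84) higher.

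Markers of haemocytes, muscle, gut and the male reproductive tract were lower on the paraquat array. Haemocyte markers had a median of -0.80 over 10 genes (percentile 0.01, random range -0.38 to 0.50), led by the collagen IV genes Col4a1 (3.67-fold lower) and vkg (3.21-fold lower), then PPO1 and PPO2 (2.02-fold lower). The head fat body median (-2.79) was lower on the same array, and whether the number of haemocytes differed was not tested. Muscle markers had percentile 0.475 (random range -0.47 to 0.44), with 3 of 11 at least 2-fold lower, Mlc2 (3.60-fold), TpnC41C (3.01-fold) and Mlc1 (log2 -1.14), and Act79B 1.94-fold lower. Gut digestive enzymes had a median of -0.62 over 16 genes (percentile 0.07, random range -0.31 to 0.38), with LysE (3.44-fold), Jon74E (2.90-fold) and Jon99Fii (2.55-fold) lower and Amy-d 2.68-fold higher. In the male reproductive tract list, the 3 genes measured on both arrays were Mst84Da (2.99-fold lower), Mst87F (2.69-fold lower) and Mst84Dc (1.80-fold lower), for a median of -1.43 (percentile 0.42, random range -0.84 to 0.75). Another 16 were above the floor on the unexposed array alone, and with these kept at the floor the median was -1.11. Among the female-specific products, Yp1 was at least 4.43-fold lower and not above the highest absent control on the paraquat array, Yp2 (0.74), Vm34Ca (-0.32) and Yp3 (-0.26) differed less, and the median of 6 genes was -0.12, inside the random range.

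**Figure D4:**
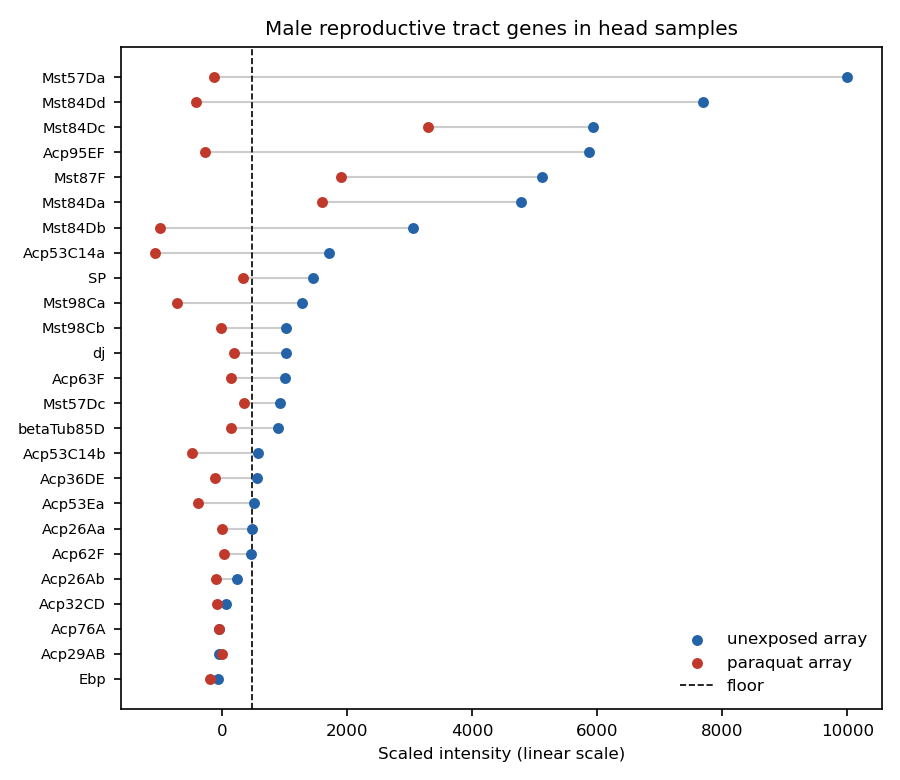
Scaled intensity (linear scale) of 25 probe sets for male reproductive tract genes on the unexposed array (blue) and the paraquat array (red), joined per gene, with the floor as a dashed line. Of these, 19 reached the floor on the unexposed array and 3 on the paraquat array, and Mst57Da stood at 9999 against -128.

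In all, 15 of 32 list medians lay outside the random range, 4 above and 11 below, where random gene lists would give 1.6. Some lists share genes, and genes of a tissue or complex can vary together between any 2 samples, so this excess is no test. Probe sets of the same gene differed by a median of 0.49 in log2 ratio over 451 pairs, against 0.63 for random pairs matched on level, and 64 of 93 pairs with a probe set past 2-fold had the same sign (68.8%). Probe sets for 18S ribosomal RNA, a residue of poly(A) purification, were about equally lower on the paraquat array in all 3 regions (log2 -1.01 to -0.92). The ratio of 3' to 5' signal, a sign of RNA integrity, was lower on the paraquat array for each control transcript, at 2.48 against 2.74 for GAPDH, 9.79 against 11.7 for eIF-4a and 11.8 against 15.3 for actin. With the floor at the 80th percentile the haemocyte median (-0.32) was inside the random range, and antimicrobial peptides (2 genes) and the male reproductive tract were too few to place.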

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

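The search among probe sets left out of the named genes, and the tests below of fat body amount, diet, muscle amount, body parts and background, were chosen only after the results they bear on had been seen, and the fat body test is the last of several forms tried. The first, against array error, was set aside because that error does not hold the variation between flies. The loess correction was planned.

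Signals of at least 16-fold on the paraquat array appeared in 4 probe sets that name several genes or none, which the comparison of named genes does not use. A probe set shared by Hsp70Bbb, Hsp70Bc, Hsp70Bb and Hsp70Ba was at least 57.1-fold higher, from 209 to 27260. A probe set shared by the same 4 genes and CG5608 was 49.6-fold higher, from 572 to 28383. A probe set shared by Hsp22 and CG4456 was 25.2-fold higher, from 2195 to 55282. A probe set with no gene named here was at least 23.3-fold higher, from -97 to 11099.

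Fat body and antimicrobial transcripts were lower on the paraquat array. For the fat body a brightness trend is argued against, since the median of -2.79 lay below random lists matched on level (-0.74 to 0.47). After loess the fat body median was -2.69, below the random range of -0.68 to 0.51. The loess result adds little, because the random lists were already matched on level. With fit at its bound, the log2 ratios of 7 markers ran from Lsp2 (-7.72) and fit (at most -6.59) through Obp99b (-2.89) and apolpp (-1.97) to Apoltp (0.45). Their SD was 2.78 (random lists 0.28 to 1.70), and at least 2.32 without any 1 of them, still above the random range. This argues against a fall of all 7 transcripts by 1 common factor. It does not decide on loss of fat body tissue, because a marker also made in other tissues would fall less. Over the measured markers alone, the form tried before, the SD was 2.69 (random lists 0.25 to 1.80), but 1.66 without Lsp2, inside the 0.22 to 1.72 of random lists. Without Lsp2 the wide spread thus rests on fit, and a smaller amount of fat body stays open as a cause. Sucrose in place of food may also contribute. The fasting list could not decide, because it mixes genes that fasting raises with genes that it lowers, so opposite changes can cancel in its median. That median was 0.041 over 9 genes that went both ways (random range -0.44 to 0.51) and -0.05 with members kept at the floor. Among those members were fit and tobi, at least 96.5-fold and 70.7-fold lower, and InR, at least 3.59-fold higher. Without a plain-sucrose array here, diet and paraquat cannot be told apart for these genes. Male reproductive tract (92.0% of 25) and gut (85.3% of 34) probe sets were also higher on the unexposed array. Body parts in that sample, considered below, were not tested as a source of the fat body and antimicrobial transcripts and stay open.

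Transcripts of the respiratory chain and ATP synthase were lower on the paraquat array in 46 of 47 genes. A brightness trend is argued against, since the median of -0.66 lay below random lists matched on level (-0.32 to 0.05). After loess the median was -0.56, below the random range of -0.24 to 0.16. The loess result adds little, because the random lists were already matched on level. Less muscle in the paraquat sample could contribute, and the test did not decide: muscle markers minus respiratory chain genes gave a difference of medians of -0.017 (95% bootstrap interval over genes -0.49 to 0.42). Of 21 muscle probe sets, 76.2% were higher on the unexposed array, against 28.6% to 71.4% for random lists. Body parts in that sample thus stay open as a source of muscle, untested for these genes. Muscle amount from either source and a response to paraquat or diet cannot be told apart here, because muscle and respiratory chain genes were lower by about the same factor.

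Transcripts of the male reproductive tract were more abundant on the unexposed array, where Mst57Da reached 9999, Mst84Dd 7689 and Acp95EF 5863. A background difference at low intensity is argued against, since 92.0% of 25 probe sets were higher there, and random lists matched on intensity gave 32.0% to 68.0%. Body parts that passed the sieve meant to hold back bodies are a candidate source: of 34 gut enzyme probe sets, 85.3% were higher on the unexposed array, against 32.4% to 67.6% for random lists. For the gut enzymes diet stays open as well, untested here. Amy-d, also of the gut, differed the other way.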

How the results depend on the processing

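The floors at the 30th and 80th percentiles and the restriction to ratios beyond the 95% interval of array error were chosen only after the results had been seen. No paired analysis was possible because each group held 1 array. The planned floor at the 20th percentile gave no value, since the intensity there was -20.4 and has no log. The 2-fold counts (605 higher, 610 lower) stayed within 1.5 times under the 4 other scalings, the pseudocount, the 30th percentile floor and the array error restriction, between 425 and 882 higher and between 455 and 871 lower. They were 290 and 317 with the floor at the 60th percentile and 132 and 156 at the 80th, where fewer probe sets were counted (4846 and 2322), 1421 and 1289 at a ratio of 1.5, and 176 and 230 at a ratio of 3. The error of a list median was taken as the distance from the middle to the end of its 95% bootstrap interval over genes. Among list medians, 343 alternative values moved by less than this error and 4 by more: the respiratory chain under quantile normalization (-0.53), ribosomal proteins under quantile normalization (0.11) and loess (0.19), and photoreceptors under quantile normalization (0.12), and the cause was not tested. All 15 lists outside the random range stayed there under the 4 other scalings, the pseudocount, the 30th percentile floor, the brightest probe set and members kept at the floor. The scalings had little room to change this. Unscaled and trimmed-mean values shift all log2 ratios, those of the random lists included, by about the same amount. Loess and quantile normalization adjust by intensity level, on which the random lists were already matched. The floor at the 60th percentile kept 11 and the 80th kept 8, with fewer genes per list, and the mean in place of the median kept 14, without the NADPH-producing enzymes. Lists inside the range came to lie outside it as well: heat shock cognates and ER chaperones under quantile normalization and loess, ribosomal proteins under loess and the 80th percentile floor, the fasting list under both higher floors, the apoptosis and JNK list under the 60th percentile floor and UDP-glycosyltransferases under the 80th. Medians turned sign for the heat shock cognates under both higher floors, for UDP-glycosyltransferases under the 80th and with members kept at the floor, for metallothioneins and iron proteins under the 80th, for the fasting list with the pseudocount and with members kept at the floor, and for photoreceptors under quantile normalization and loess. Of the values of named genes, 40 with the floor at the 60th percentile and 79 at the 80th were no longer measured on both arrays. Of the others, 1081 stayed within the 95% interval of array error and 8 moved beyond it, among them tim, which turned sign with the pseudocount (0.10). Many of these values had little room to move, so the tally is weak evidence of stability. A change of floor leaves the ratio of a gene with 1 measured probe set as it was. The unscaled and trimmed-mean values shift all ratios by about the same small amount. The 12 highest and 12 lowest genes remained in their sets under the other scalings, apart from 1 of the highest under quantile normalization, and 8 and 8 remained with the pseudocount, 8 and 9 with the floor at the 30th percentile, 6 and 5 at the 60th, and 2 and 0 at the 80th. Intensity over background limits the dim genes most, since the array error was 1.54 at the floor and 0.19 at 10 times the floor.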

Other observations

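The gene families below were grouped by gene name and set against random lists only after the results had been seen. Cytosolic aminoacyl-tRNA synthetases, the CCT chaperonin and translation initiation factors had higher medians on the paraquat array, whereas mitochondrial ribosomal proteins (mRpL -0.06, mRpS 0.02) and prefoldin subunits (Pfdn 0.47) lay inside the random range. Of 15 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 14 were higher and 9 at least 2-fold higher, with a median of 1.40 above all 10000 random medians. TrpRS (9.93-fold), SerRS (5.21-fold) and ThrRS (4.28-fold) led, while the 8 mitochondrial synthetases had a median of 0.18 inside the random range. All 7 measured subunits of the CCT chaperonin, which folds actin and tubulin, were higher, 4 of them at least 2-fold, with a median of 1.11 and CCT5 at 4.08-fold. Of 30 translation initiation factors 23 were higher, 6 of them at least 2-fold, and 7 were lower, with a median of 0.39. The highest were eIF6 (5.72-fold), eIF2beta (4.32-fold) and eIF2Bepsilon (4.09-fold).

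The 8 measured genes named as juvenile hormone binding proteins (Jhbp) were all lower on the paraquat array, 5 of them at least 2-fold, with a median of -1.44 below all random medians. Jhbp13 was 9.68-fold lower and Jhbp14 8.36-fold lower. Head fat body (-2.79), male reproductive tract (-1.43), muscle (-0.67) and gut enzyme (-0.62) medians were lower on the same array. The cytosolic synthetase, CCT, initiation factor and Jhbp families stayed outside the random range, in the same direction, under all 8 settings tried for scaling, floor and pseudocount. The scaling settings had little room to change this, as described above for the lists. Another 4 families were outside it at the main setting and not under every other: Nim (median 1.06), Nup (0.48), Oatp (-1.18) and yellow (-1.05). With the floor at the 60th percentile Nim and Oatp turned sign, at -0.38 over 2 genes and 0.24 for 1 gene. In all, 79 families of at least 5 genes were compared and 16 lay outside the random range, where random gene lists would give 3.95. Of the 16, 8 shared no gene with the lists fixed in advance. Families are not independent: Prosalpha, Prosbeta, Rpn and Rpt, all of the proteasome, count separately, so this excess is no test.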
